A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

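Two-colour microarrays of total RNA from Saccharomyces cerevisiae were analysed from the 6 columns of the deposited value table, each 1 array with the met4 mutant in Cy3 and the wild type in Cy5 per the labels. Every column was matched to its sample by accession, and no other column of sample values was present (0). The deposited values are log ratios of the 2 channels for 13056 spots, taken as log2. The array platform's printing, scanner, background correction and image software are not given in the sources used here. No scanner intensities were used here, so spots near background could not be marked and no intensity-dependent (loess) correction could be made.

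The scale was judged from the values. The deposited log ratios ran from -3.57 to 5.32. A base of 10 would make the highest a 211208-fold ratio, beyond the range of a scanner channel, so log2 was assumed, but a natural logarithm cannot be excluded. In that case each value would be 1.44 units on the log2 scale per unit printed, with the same tests and directions. The array medians lay between -0.95 and 0.92, so the deposited values were not centred. Exact zeros occurred at 134 spots, 6 of them named and belonging to the abundant transcripts TDH3, RPL8A, CDC19, TDH1 and SSA1, and were set to missing. The numerator of the ratio is not stated. The rule fixed before the data were examined was to call mutant over wild type likely if MET4 was below 0 on every array. It did not hold for the values as deposited (MET4 was at 0.59 on array 3), for which the rule would have given sizes without a direction, and it held after centring.

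The plan fixed before the data were examined used the values as deposited, with centring on the array median as an alternative. After the array medians were seen, and before any test was run, centring was made the reported setting because it removes an offset between the channels. The values of MET4 and of a few sulfur and marker genes had been seen by then. Where the call of a named gene or a list differed in the values as deposited, this is said beside it.

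Spots were named through the platform annotation, in which 11138 spots carry 1 gene symbol each, none carries several and 1918 have none. Its gene identifiers matched the R64 gene table for all but 5 genes. Neighbouring spots of 1 gene numbered 5569 pairs, with r of 0.899 to 0.984 within arrays. This shows that duplicate spots gave similar values, but not that each pair carries the right gene name. Because no genome build was named in the sources used here, no coordinates are given. All spots of a gene were averaged per array, giving 5539 genes, with a value on at least 4 of 6 arrays required, which removed none (0). Unnamed spots entered the array medians but no test.

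Each gene's mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit on an intercept, eBayes) and Benjamini-Hochberg adjustment over all genes, at an adjusted p of 0.05. No dye term could be fitted because 0 arrays had the dyes swapped. The calculation was tested on simulated log ratios for this comparison with 5539 genes, of which 200 were changed. It recovered 37.3% of changes of 0.5, 80.6% of changes of 1 and 100% of changes of 2 on the log2 scale, and 2 of 147 calls were false. The simulated noise was normal and independent between genes and arrays. In the real data genes vary together and arrays may share cultures, so these rates need not hold there. The 23 gene lists, written before the data were examined from general knowledge of yeast, were each compared with the other genes by camera with a preset correlation of 0.01, two-sided, adjusted over the lists, then with an estimated correlation and with fry. Camera passed 11 lists at the preset correlation and 0 with an estimated one (the general stress list and the phosphate regulon had unadjusted p = 0.0357 and 0.0314). Fry, which asks whether a list's own genes move one way on balance, passed 3 (general stress, ribosomal proteins and the phosphate regulon). Some genes, 11 in all, stand in more than 1 list. Single genes and MET4 were also tested by exact two-sided sign-flip permutation over the 64 sign patterns.

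Named genes were chosen by a rule fixed before the data were examined: MET4, the 12 highest and the 12 lowest genes past the threshold with the same sign on all arrays, up to 4 members per list by size among those past the threshold (if none passed, the 1 with the smallest adjusted p), and any member of the sulfur and arsenic lists. Alternatives were the values as deposited, arrays scaled to the same median absolute deviation, quantile normalization, other limits on missing values, leaving out each array, robust empirical Bayes, array weights and 1 row per gene. Those added after seeing the data were centring of 48 equal runs of consecutive spots (print-order runs), keeping the exact zeros, averaging arrays in pairs and reading the values as natural logarithms. Figures were drawn with matplotlib 3.10.9.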

Results

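Gene expression of a met4 deletion mutant of Saccharomyces cerevisiae was compared directly with that of the wild type, both exposed to 0.2 mM arsenite, As(III), for 1 hour. Met4 is the transcriptional activator of the genes for sulfate assimilation and sulfur amino acid synthesis, the pathways that also supply glutathione, which binds arsenite. The comparison therefore asks which transcripts differ between mutant and wild type in arsenite-exposed cells. All 6 arrays were hybridisations of the mutant in the Cy3 channel against the wild type in the Cy5 channel, and they form 1 group of 6 replicates. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical. No unexposed cells were among the arrays analysed, so a difference that already existed without arsenite cannot be separated from one that arose in it.

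Each array gave a log ratio for 13056 spots, of which 11138 were named and represented 5539 genes. The precision is limited by the number of arrays. Spots of the same gene printed side by side correlated across spots with r between 0.899 and 0.984 within an array, whereas the arrays correlated across genes with r between 0.0817 and 0.759 (median 0.448 over 15 pairs). Genes are not independent replicates, and these values only describe the arrays. Array 2 stood furthest from the rest, with a mean r of 0.291. Arrays 3 and 5 had the highest r of all pairs, 0.759, and arrays 4 and 6 had 0.609. The median SD between arrays was 0.35 per gene on the log2 scale.

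The deposited log ratios were not centred: the array medians were 0.32, 0.36, 0.92, -0.32, 0.36 and -0.95 on arrays 1 to 6. The values below are log2 ratios after each array was centred on its median, given as mean ± SD over n = 6 arrays. Centring moved the median of all gene means from 0.12 to 0.0053, so changes are relative to the typical gene. The sources used here state neither the log base, taken as 2, nor which channel is the numerator. A direction of mutant over wild type is called likely, on the basis of the order in the sample titles and of the centred MET4 values. The rule fixed beforehand asked for MET4 below 0 on every array, and the values as deposited did not meet it. "Higher" and "lower" below carry that proviso. Every array had the same dye orientation, so a dye bias of single genes cannot be separated from the effect of the mutation.

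MET4 (YNL103W), the gene deleted according to the series title, stood at -0.59 ± 0.25 (SD, n = 6) and was below the array median on 6 of 6 arrays (limma, adjusted p = 0.0112; exact two-sided sign-flip permutation test, p = 0.0312, the smallest that 6 arrays allow). Its level lay between -0.94 on array 2 and -0.32 on array 6. It stood at the 24.0th percentile of genes on array 3 and the 19.7th on array 6, so it was not among the lowest genes there. The deposited value was above 0 on array 3, at 0.59, where the array median was 0.92, and the mean of the deposited values, -0.47, was not past the threshold (limma, adjusted p = 0.600). The labels do not give the deleted part of the gene or the sequence on the array, so the spots may lie partly outside the deletion. The MET4 values alone do not show that the transcript was absent.

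In arsenite-exposed cells the mutant had lower transcript levels of MET17, of 4 of 10 sulfate assimilation genes and of 106 of 132 ribosomal protein genes. It had higher levels of 20 of 30 general stress genes, and the single highest gene was INO1. Each of these 3 lists differed from other genes by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.403 for each). Of 5539 genes tested, 836 differed between mutant and wild type (limma, adjusted p under 0.05), of which 521 were higher and 315 lower in the mutant. The change was at least 2-fold for 102 higher and 69 lower genes, and this split varied with the setting: it was 152 above 0 and 45 below 0 as deposited, 155 and 50 without array 2, and 94 and 94 without array 4. If the values were natural logarithms, 434 genes would reach 2-fold, 268 higher and 166 lower. The same sign on all 6 arrays was found for 1001 genes, 18.1% of those tested, and 626 of the 836 were among them. Chance gives 3.12% if the arrays are independent. Arrays that share a culture, or a dye bias common to all, would give a higher share. As deposited, without centring, 246 genes passed, 187 above 0 and 59 below 0, and 235 of them were among the 836. The share of calls below 0 was 24.0% as deposited and 37.7% after centring, and if wild type were the numerator these would be the shares of genes higher in the mutant. Leaving out array 3, 5 or 6 reduced the calls to 456, 518 and 528 and the higher genes to 291, 327 and 293, and leaving out array 1, 3 or 5 reduced the lower genes to 208, 165 and 191.

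**Figure D1:**
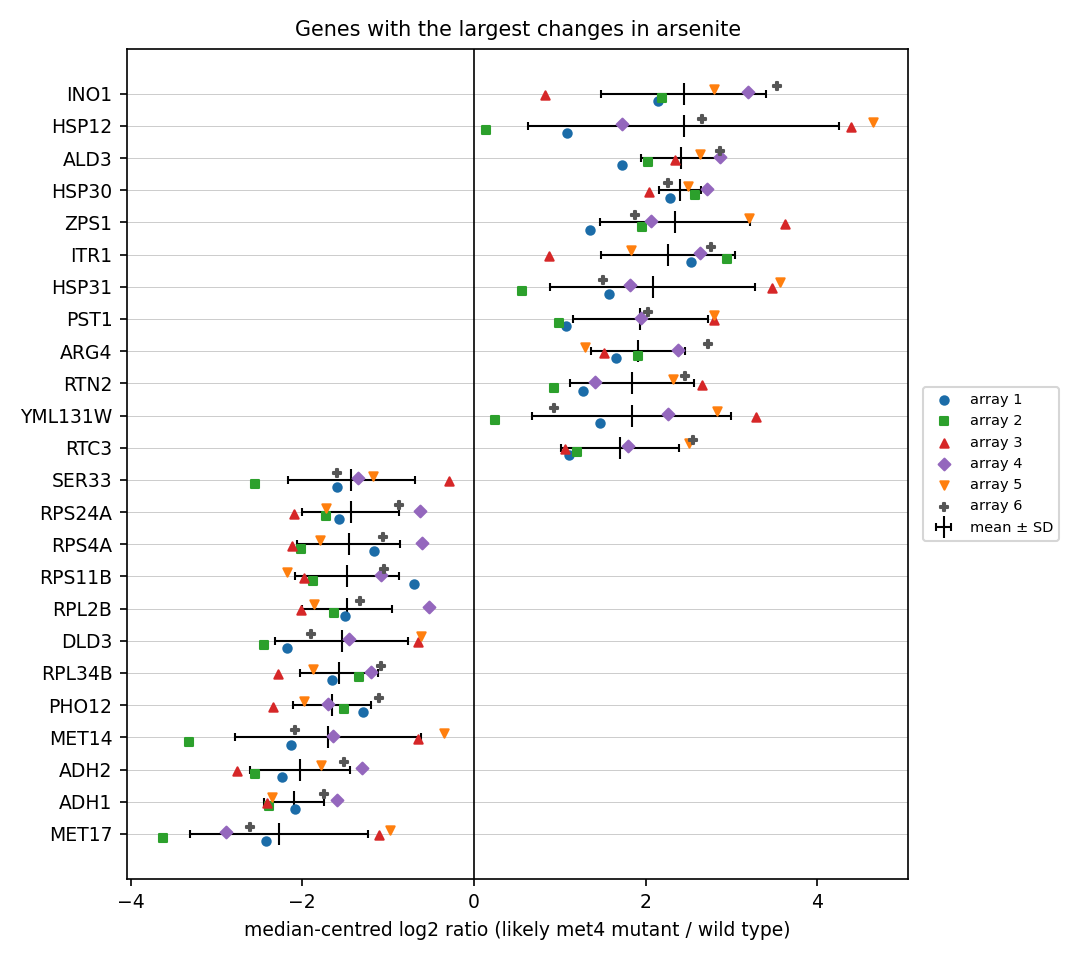
Median-centred log2 ratio (x axis, likely mutant over wild type) of the 12 highest and 12 lowest genes past the threshold with the same sign on all 6 arrays. Symbols are arrays and bars are mean ± SD; INO1 and ITR1 were less high on array 3 than on the other arrays, and MET17 and MET14 less low on arrays 3 and 5.

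Among the highest genes, INO1 (YJL153C), which encodes inositol 3-phosphate synthase, stood at 2.45 ± 0.96 (limma, adjusted p = 0.000249), and ITR1, the major inositol transporter, at 2.26 ± 0.78. The stress genes HSP12 (2.44 ± 1.81), ALD3 (2.41 ± 0.47), HSP30 (2.40 ± 0.24) and HSP31 (2.08 ± 1.19) were higher as well. HSP30 encodes a plasma membrane heat shock protein and ALD3 a stress-induced aldehyde dehydrogenase. The remaining 6 were the cell surface genes ZPS1 (2.35 ± 0.87) and PST1 (1.94 ± 0.79), the arginine synthesis gene ARG4 (1.91 ± 0.55), and RTN2 (1.84 ± 0.72), YML131W (1.84 ± 1.16) and RTC3 (1.70 ± 0.69). Of these 12 genes HSP12 varied most between arrays, from 0.14 on array 2 to 4.65 on array 5.

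The lowest gene of all was MET17 (YLR303W), which encodes O-acetylhomoserine sulfhydrylase, at -2.27 ± 1.04 (limma, adjusted p = 0.000493). ADH1, the main fermentative alcohol dehydrogenase, stood at -2.10 ± 0.35 and ADH2 at -2.03 ± 0.59. These are close paralogs, and the probe sequences were not used here, so a signal shared between them cannot be excluded. The acid phosphatase gene PHO12 (-1.66 ± 0.46), DLD3 (-1.54 ± 0.78) and SER33, a serine synthesis gene (-1.43 ± 0.73), were lower too. So were MET14 and the ribosomal protein genes RPL34B (-1.57 ± 0.45), RPL2B (-1.48 ± 0.53), RPS11B (-1.48 ± 0.61), RPS4A (-1.46 ± 0.60) and RPS24A (-1.44 ± 0.56), several of which have a nearly identical copy.

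Of 10 genes for sulfate assimilation, the uptake of sulfate and its reduction to sulfide, 4 fell, none rose and 6 did not pass. MET14 (adenylylsulfate kinase) fell by 1.70 ± 1.08, MET16 (phosphoadenylylsulfate reductase) by 1.36 ± 1.26, MET3 (ATP sulfurylase) by 1.31 ± 1.35 and MET5 (sulfite reductase) by 0.91 ± 0.60 on the log2 scale. SUL2, a sulfate permease, stood at -0.55 ± 0.61 (adjusted p = 0.0786) and SUL1, the other permease, at 0.07 ± 0.60. MET10, MET1, MET8 and MET22 had means of -0.19, -0.21, -0.33 and -0.18. Adjusted over the list alone, 5 members were lower. The list was lower than other genes by camera (median -0.44, adjusted p = 0.000874), but not with an estimated correlation (adjusted p = 0.403). The list median was -0.06 on array 3 and 0.09 on array 5, and -0.41 or lower on the other 4 arrays. The MET3 call was lost without array 4 (limma, adjusted p = 0.0747) or array 6 (0.121), the MET16 call without array 1 (0.0523) or array 6 (0.0569), and the MET5 call in the values as deposited (0.141). MET16 also missed the threshold with centring by print-order run, and MET3 and MET16 missed it with robust empirical Bayes.

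In the methionine and S-adenosylmethionine cycle, 4 of 16 members fell and none rose, with the same count adjusted over the list alone. Besides MET17 these were HOM6, homoserine dehydrogenase (-0.73 ± 0.47), MHT1, S-methylmethionine-homocysteine methyltransferase (-0.61 ± 0.53), and MET2, homoserine O-acetyltransferase (-0.49 ± 0.39). MET6, the methionine synthase, stood at -0.18 ± 0.72, SAM1 and SAM2 at 0.11 ± 0.81 and -0.04 ± 0.35, and HOM3 at 0.33 ± 0.60, which passed as higher without array 2 (limma, adjusted p = 0.0144). As a whole the list was not past the threshold by camera (median -0.16, adjusted p = 0.0607). It passed without array 3, 4 or 6 (0.0280, 0.0448 and 0.0380), as deposited (0.00980) and with centring by print-order run (0.0265), but not with an estimated correlation (adjusted p = 0.403). Without array 2 its median was -0.03 (adjusted p = 0.353). The calls of HOM6, MHT1 and MET2 did not hold in the values as deposited. HOM6 also missed the threshold without array 6 (limma, adjusted p = 0.0511), while MHT1 held only without array 5 and MET2 only without array 4, and both missed it with centring by print-order run. MHT1 missed it also with arrays scaled to the same spread.

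For cysteine and glutathione synthesis, CYS4, cystathionine beta-synthase, fell by 1.28 ± 0.57 (limma, adjusted p = 0.00113, lower on 6 of 6 arrays). STR2, a cystathionine gamma-synthase, rose by 0.47 ± 0.21, a call that did not hold as deposited or without array 1, 3 or 5. The other 5 of the 7 members did not pass, and the counts were the same adjusted over the list alone. Among these, CYS3 stood at -0.29 ± 0.73 and the glutathione synthesis genes GSH1 and GSH2 at 0.31 ± 0.54 and 0.22 ± 0.49. The list showed no shift by camera (adjusted p = 0.747), and its median of 0.0041 and mean of -0.11 differed in sign.

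Among 17 genes for uptake and scavenging of sulfur compounds, 1 passed and it rose: ECM38, gamma-glutamyltranspeptidase (0.76 ± 0.45; limma, adjusted p = 0.00925, and 0.0821 as deposited). The methionine permease gene MUP1 stood at -0.55 ± 0.65, SEO1 at -0.51 ± 0.46, OPT1, a glutathione transporter, at -0.42 ± 0.28 and SOA1 at -0.40 ± 0.29. Adjusted over the list alone, 3 members were lower and 1 higher. The list median was -0.21 (camera, adjusted p = 0.0607, which became 0.0182 without array 3 and 0.0181 without array 5), and it also passed with centring by print-order run (0.0366) and with array weights, but not with an estimated correlation (adjusted p = 0.403). Of 9 genes of the Met4 complex and its regulators, the cofactor MET28 (-0.43 ± 0.27) and MET4 itself were lower and the ubiquitin ligase genes CDC34 (0.63 ± 0.52) and CDC53 (0.51 ± 0.37) higher, with the same counts adjusted over the list alone (camera for the list, adjusted p = 0.421). None of these 4 calls held in the values as deposited. MET28 lost its call without any 1 array, CDC53 without any array but array 2, and CDC34 without array 3, 4, 5 or 6. CDC34 and MET28 also lost theirs with centring by print-order run, while MET4 kept its call there and without each array in turn.

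**Figure D2:**
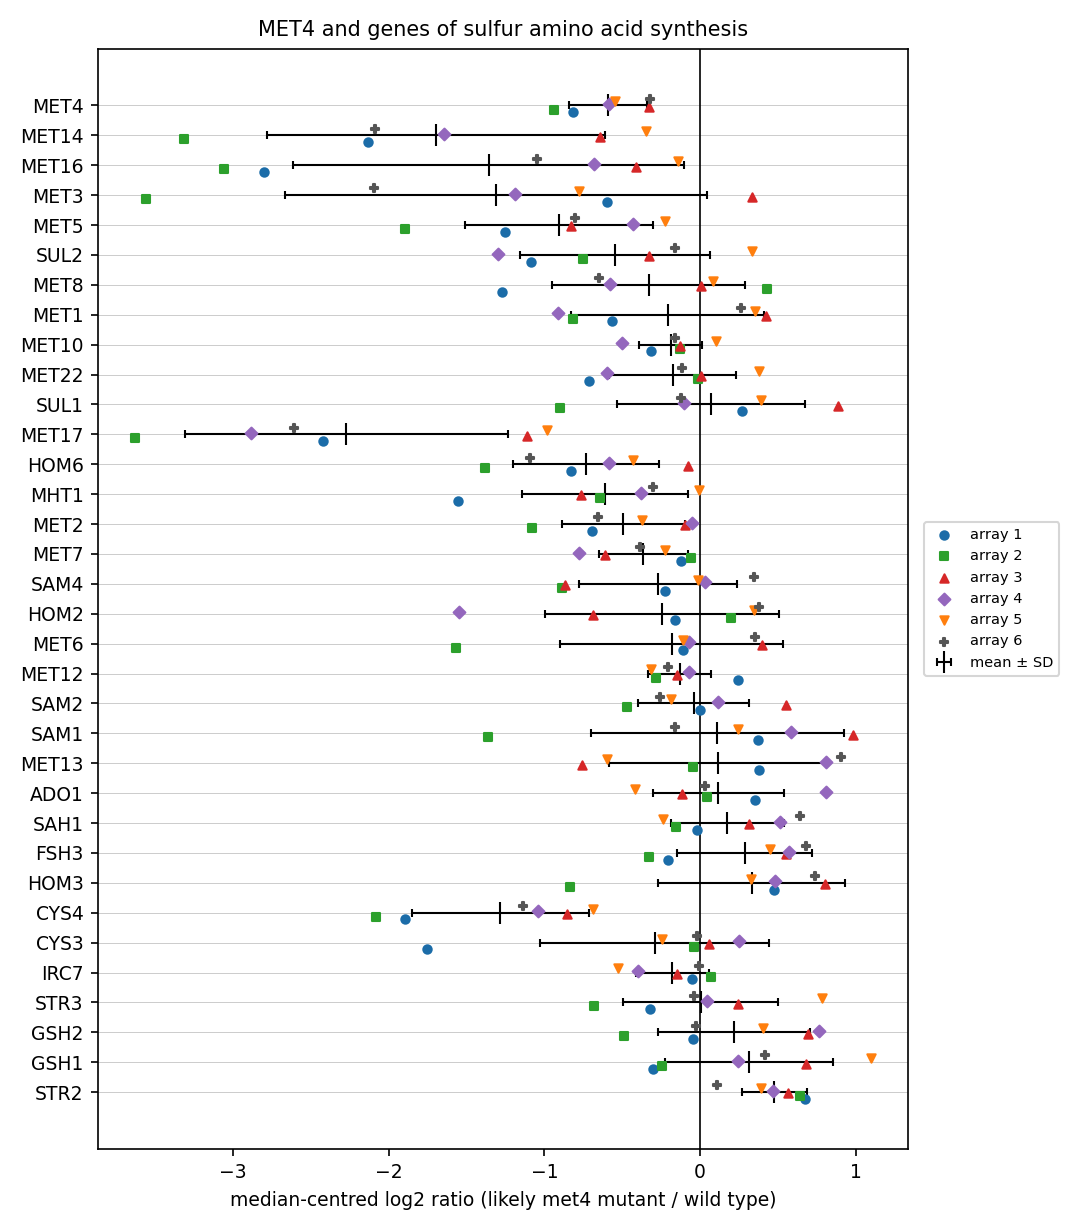
Median-centred log2 ratio (x axis, likely mutant over wild type) of MET4 and of the members of the lists for sulfate assimilation, methionine and cysteine synthesis, in that order. Symbols are the 6 arrays and bars mean ± SD; MET3 ranged from -3.55 on array 2 to 0.34 on array 3, and CYS4 was below 0 on all 6.

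Of 10 genes for arsenic detoxification 3 rose, none fell and 7 did not pass: ARR3, the plasma membrane arsenite exporter (0.97 ± 0.63; limma, adjusted p = 0.00757), YCF1, a vacuolar transporter of glutathione conjugates (0.45 ± 0.22), and VMR1, a related vacuolar transporter (0.59 ± 0.54). ARR2, an arsenate reductase, stood at 0.98 ± 1.15 (adjusted p = 0.0559), the activator gene ARR1 at 0.22 ± 0.33, the glutathione transferase gene GTT2 at 0.91 ± 1.35 and GTO1 at -0.55 ± 0.56. FPS1, the aquaglyceroporin through which arsenite enters, stood at 0.03 ± 0.15, and HOG1 at 0.18 ± 0.23. Adjusted over the list alone, 5 were higher and 1 lower. The list was higher by camera (median 0.41, adjusted p = 0.0290), not with an estimated correlation (adjusted p = 0.403), and not without array 3 (0.0660) or array 5 (0.0562). YCF1 and VMR1 were not called in the values as deposited, YCF1 held only without array 2 and VMR1 only without array 4. YCF1 missed the threshold with 1 row per gene and VMR1 with centring by print-order run, and ARR2 and GTT2 passed as deposited (adjusted p = 0.0140 and 0.0261).

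Of 30 general stress targets of Msn2 and Msn4, 20 rose and 1 fell (23 and 2 adjusted over the list alone), with a median of 0.95 that was above 0 on 6 of 6 arrays. Besides HSP12, ALD3 and RTN2, the catalase gene CTT1 stood out at 1.70 ± 1.67, although it was at -1.04 on array 2 and lost its call without array 1, 3, 5 or 6 (limma, adjusted p up to 0.0761). Of 28 oxidative stress targets of Yap1, 10 rose and none fell (13 adjusted over the list alone), led by OYE3 (1.73 ± 1.64), AAD14 (1.58 ± 1.55), GRX2, a glutaredoxin (1.25 ± 1.16), and SOD1, superoxide dismutase (1.10 ± 1.04). Each of these 4 was below 0 on array 2 and lost its call without array 3 (adjusted p 0.0688, 0.0828, 0.0684 and 0.0866), AAD14, GRX2 and SOD1 also without array 5 or 6, and AAD14 and SOD1 without array 4. CTT1 and these 4 also missed the threshold with centring by print-order run, and CTT1, OYE3 and AAD14 with robust empirical Bayes. Both lists were higher by camera (adjusted p = 8.32e-11 and 1.57e-05), and neither with an estimated correlation (adjusted p = 0.403 for each).

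Of 38 genes for the proteasome and its activator, 11 rose, none fell and 27 did not pass (18 adjusted over the list alone). RPN4, the activator, stood at 1.41 ± 0.45, and the subunit genes SCL1, RPT3 and PRE6 at 1.13 ± 0.63, 1.07 ± 0.43 and 1.04 ± 0.69. Of 28 genes in the list of Hsf1 chaperones, 8 rose, none fell and 20 did not pass (9 adjusted over the list alone). The largest was HSP30, whose product is the plasma membrane protein described above and not a chaperone. The next were the disaggregase gene HSP104 (1.10 ± 0.66), HSP26 (1.03 ± 0.71) and CUR1 (0.99 ± 0.45). Camera gave adjusted p = 6.59e-08 and 0.000905 for these lists, and with an estimated correlation adjusted p = 0.403 for both. The medians of both lists, 0.48 and 0.32, were below 0 on array 2 alone.

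Of 132 ribosomal protein genes measured, 106 fell, none rose and 26 did not pass (122 fell adjusted over the list alone). Their median was -0.88 and was below 0 on 6 of 6 arrays, nearest to it on array 4 at -0.25. Of 44 genes for ribosome biogenesis, 13 fell and none rose (19 adjusted over the list alone), including RRP9 (-0.71 ± 0.43), NOP56 (-0.71 ± 0.46), NOP2 (-0.70 ± 0.50) and DBP3 (-0.69 ± 0.41), none of which was called as deposited. NOP2 also lost its call without array 1 or 3. Both lists were lower by camera (adjusted p = 1.76e-47 and 6.58e-09), and with an estimated correlation adjusted p = 0.403 for each.

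**Figure D3:**
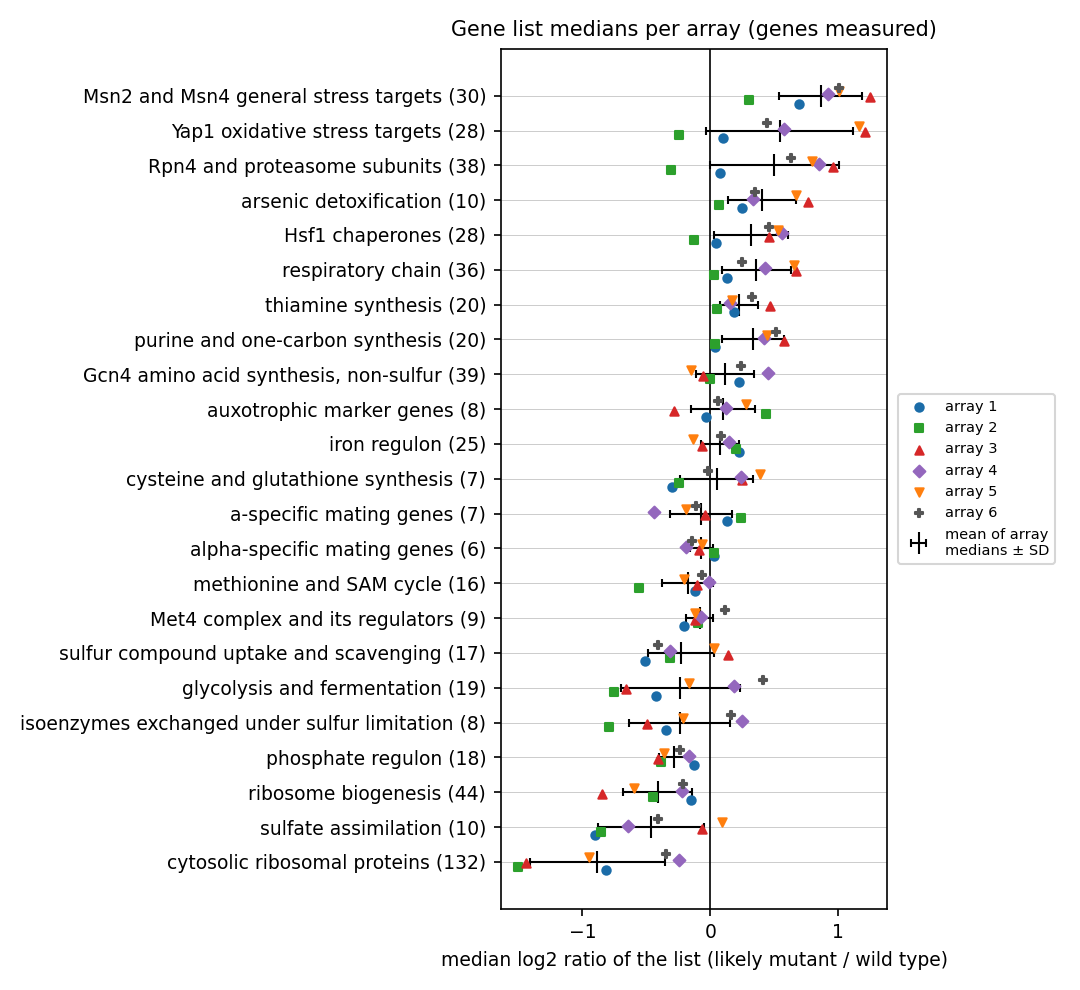
Median log2 ratio (x axis, likely mutant over wild type) of the members of each of the 23 gene lists on each array, with the number of genes measured in parentheses. Symbols are arrays and bars the mean of the array medians ± SD; the general stress median was above 0 and the ribosomal protein median below 0 on all 6 arrays, while sulfate assimilation stood at -0.06 on array 3 and 0.09 on array 5.

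Of 36 respiratory chain genes, 9 rose, none fell and 27 did not pass (14 adjusted over the list alone), led by QCR7 (0.95 ± 0.67), CYC1 (0.93 ± 0.45), SDH1 (0.87 ± 0.64) and NDE1 (0.87 ± 0.27). Of 18 phosphate regulon genes, 6 fell and 2 rose (8 and 3 adjusted over the list alone). PHO12 and SPL2 (-1.22 ± 0.60) held as deposited, and the polyphosphate synthesis genes VTC1 (-0.81 ± 0.36) and VTC4 (-0.79 ± 0.19) did not. Of 19 genes for glycolysis and fermentation, 6 fell, 1 rose and 12 did not pass, with the same count adjusted over the list alone: ADH1, ENO1 (-1.11 ± 0.82) and GPM1 (-0.75 ± 0.73) were lower and the glycerol synthesis gene GPD1 (1.55 ± 0.52) higher. The glycolysis median was above 0 on arrays 4 and 6 (0.18 and 0.41) and below 0 on the other 4 arrays, and the list median of -0.26 was -0.17 without array 2 (camera, adjusted p = 0.0456). GPM1 was not called as deposited, with centring by print-order run, or without any array but array 5. Camera placed the respiratory chain higher than other genes and the phosphate regulon and glycolysis lower (adjusted p = 1.57e-05, 0.00109 and 0.00513), and with an estimated correlation adjusted p = 0.403 for each.

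In amino acid synthesis outside sulfur metabolism, 5 of 39 Gcn4 targets rose and 4 fell (6 and 5 adjusted over the list alone; camera, adjusted p = 0.219). The arginine genes ARG4, ARG1 (1.48 ± 0.44) and ARG3 (1.12 ± 0.87) were higher and SER33 lower, and ARG3 lost its call without array 6 (limma, adjusted p = 0.0551). Of 20 purine and one-carbon genes, 6 rose and none fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.0607, 0.0217 without array 1 and 0.0147 as deposited, but adjusted p = 0.403 with an estimated correlation). These included the glycine cleavage genes GCV1 (1.16 ± 0.60), GCV2 (0.90 ± 0.63) and GCV3 (1.05 ± 0.97), and SHM2 (0.84 ± 0.85). GCV3 lost its call without array 3, 5 or 6, SHM2 without array 3, 4, 5 or 6, and both with centring by print-order run. Of 20 thiamine and pyridoxine genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera, adjusted p = 0.0607), a list that passed with array weights, not with an estimated correlation (adjusted p = 0.403), and whose median of 0.27 was 0.11 with centring by print-order run. The members named were SNZ1 (1.49 ± 0.88), SNZ2 (0.96 ± 0.92), SNO1 (0.60 ± 0.36) and the thiamine-repressible phosphatase gene PHO3 (-1.07 ± 0.59). SNZ2 was not called without array 3, 4, 5 or 6, and SNO1 not without array 3 or 6 or as deposited.

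Among isoenzymes known to be exchanged under sulfur limitation, 1 of 8 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.0624, and 0.0311 and 0.0214 without arrays 4 and 6), and the list also passed with array weights. Its median of -0.31 was -0.19 without array 2 (adjusted p = 0.280), and with an estimated correlation the adjusted p was 0.484. The list holds both partners of each exchange, so neither its median nor camera tests whether an exchange took place. ALD4 was higher (1.54 ± 1.08), and ENO1, ENO2 (-0.69 ± 0.51) and PDC6 (-0.55 ± 0.28) lower. ENO2 and PDC6 were not called as deposited, ENO2 not without array 1, 3 or 6 or with centring by print-order run, and PDC6 not without array 1 or 5. The iron regulon had 1 higher and 2 lower genes of 25, also adjusted over the list alone (camera, adjusted p = 0.747), with HMX1, heme oxygenase, at 0.99 ± 0.42, SIT1 at -0.58 ± 0.48 and AFT1 at -0.44 ± 0.08. SIT1 and AFT1 were not called as deposited, nor with centring by print-order run, nor without array 1, 3, 5 or 6, and SIT1 also not without array 2 or with 1 row per gene.

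Lists that could reveal a difference in strain background were also examined. None of 7 a-specific and none of 6 alpha-specific mating genes passed (camera, adjusted p = 0.765 and 0.602; medians -0.05 and -0.11, with a mean of opposite sign, 0.06, for the a-specific list), and adjusted over the list alone none did either. The smallest adjusted p belonged to MFA1 (0.74 ± 1.42; limma, adjusted p = 0.227) and STE3 (-0.26 ± 0.39; 0.286). Of 8 genes in common use as auxotrophic markers, ADE2 (0.75 ± 0.27) and LYS2 (0.52 ± 0.23) were higher and MET17 lower, with 3 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.747; median 0.15 and mean -0.10, which differ in sign). ADE2 and LYS2 were not called as deposited, and LYS2 not without array 3 or 5.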

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

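The tests on arrays 3 and 5 were chosen, and changed, after their results were seen, while those on the ribosomal protein genes were written before. Of 155 genes and lists examined, 9 had 1 array far from the other 5, which is 5.81% where chance gives about 5%. On array 2 these were HOM3 at -0.84 (others 0.32 to 0.80), MET6 at -1.57 (others -0.11 to 0.40) and the median of the methionine and S-adenosylmethionine cycle at -0.56 (others -0.21 to -0.01). On array 4 they were SOA1 at 0.14 (others -0.73 to -0.41), CDC53 at 1.23 (others 0.21 to 0.51), AFT1 at -0.60 (others -0.44 to -0.35) and NDE1 at 1.39 (others 0.63 to 0.88). CYS3 stood at -1.76 on array 1 (others -0.25 to 0.25), and the mating pheromone gene MFA1 at 3.41 on array 6 (others -0.82 to 0.69). Among spots with no gene name, which no comparison uses, 1 neighbouring pair (spots 11825 and 11826) had a mean log2 ratio of 3.83 ± 0.57 (SD, n = 6), between 3.07 and 4.63 on the 6 arrays and above every named gene. The next unnamed pair stood at 1.79.

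The sulfur genes were less low on arrays 3 and 5 than on the others: the 50 measured genes of the 4 sulfur lists had medians of 0.03 and -0.01 there, against -0.56 to -0.16 elsewhere. Compressed log ratios on these arrays were first examined with the general stress list. Its medians of 1.25 and 1.00 there decided nothing, because array 6 lay above array 5. The Yap1 targets, taken up afterwards, had a median of 1.16 or more on both, against at most 0.58 elsewhere. This goes against compression, but a list chosen after the results were seen is weak evidence. The median absolute deviation over genes was widest on array 3 (0.53). On array 5 it was 0.40, narrower than on arrays 2, 4 and 6 (0.47, 0.52 and 0.48), so compression there is not excluded. That arrays 3 and 5 hold no met4 mutant RNA was first examined with all 50 genes. Their medians lay at the 57.1th and 37.3th percentile of random lists, as this explanation needs. It was then examined with 11 genes that were lower on the other 4 arrays, whose medians of -0.33 and -0.23 lay at the 2.90th and 3.96th percentile. Those 11 medians also lay within the central range first set, so the explanation was kept under both earlier versions and became undecided only when that range was narrowed with the values in view. Against wild type on both channels stand differences shared with the other arrays (on arrays 3 and 5, ribosomal protein medians of -1.44 and -0.95, ALD3 at 2.34 and 2.64, ADH1 at -2.41 and -2.36, CYS4 at -0.86 and -0.69, and MET17 at -1.11 and -0.98), but a dye bias common to all arrays, or another strain, would leave such differences too, and these and a difference between cultures stay open.

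The ribosomal protein genes were lower while general stress genes were higher. A bias on all abundant transcripts was examined with the glycolysis and fermentation list, whose transcripts are also abundant. Its median was -0.26 (-0.17 without array 2) against -0.88 (-0.76 without array 2) for ribosomal proteins (permutation of members between the lists, p = 1e-05, the smallest that 100000 resamples give, with genes not independent). ADH1's value had been seen beforehand. By the prediction this goes against such a bias as the whole cause, but the comparison cannot decide it. The exact zeros at TDH3, CDC19 and TDH1 may mark spots at the limit of the scanner range, where ratios shrink towards 0. The centred glycolysis medians had the opposite sign to the deposited array medians on every array, as such shrinkage would give. The medians of both lists also tended to move together across arrays, lowest on array 2 and highest on arrays 4 and 6. On arrays 4 and 6 they were 0.18 and 0.41 for glycolysis, against -0.25 and -0.35 for ribosomal proteins. No intensity-dependent correction could be made, so a bias on abundant transcripts stays open. A trend with print position is argued against, since 95.9% of the ribosomal protein median remained after centring by print-order run. Gene-specific dye bias stays open, since 0 arrays had the mutant in Cy5. An effect of the mutation on growth in arsenite was not tested.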

How the results depend on the processing

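Alternatives chosen after seeing the data were centring by print-order run, keeping exact zeros, averaging in pairs and natural logarithms. Against 836 changed genes (521 higher, 315 lower), the values as deposited gave 246 (187 and 59). The numbers from the other normalizations, filters, weights and row choices stayed within 1.5 times. A similar number did not always mean the same genes. Centring by print-order run called 850 genes, of which 604 were among the 836, while 834 of the 936 called with quantile normalization were among them. The limits on missing values removed no gene and so tested nothing. Leaving out 1 array gave 456 to 965 changed, 291 to 663 higher and 165 to 302 lower genes, the fewest without array 3. The exact sign-flip test called 0 genes after adjustment, since its smallest p with 6 arrays is 0.0312, which 1001 genes reached. Averaging arrays in pairs gave 383 to 1280 genes over the 15 possible pairings, with 383 for the pairing of the highest correlation (1 with 2, 3 with 5, 4 with 6). If these pairs shared a culture, that smaller number would be the relevant one. Of 171 genes changed at least 2-fold, 41 passed a test against 1.5-fold, and 434 would count as 2-fold if the values were natural logarithms. With an estimated correlation 0 of the 11 lists passed, sulfate assimilation (-0.45 relative to all genes) included. Relative to all genes, the methionine cycle list (-0.16) passed as deposited at -0.16 and by print-order run at -0.28, and when 1 array was left out it lay between -0.21 and -0.0346. The uptake list passed with array weights at -0.20, by print-order run at -0.29 and without array 3 or 5, and it lay between -0.23 and -0.15 when 1 array was left out. MET4 missed the threshold as deposited (-0.47). The cause of these changes was not tested, apart from the spread that the array offsets add to the values as deposited. Of the named genes not past the threshold, SUL2, MET12, JLP1 and HOG1 passed by print-order run, SOA1, SEO1, OPT1, ARR2 and GTO1 with array weights, the last 4 of these also with quantile normalization, ARR2 with 1 row per gene, and ARR2 and GTT2 as deposited. Leaving out 1 array, HOM3, OPT1, ARR2 and GTO1 passed without array 2, MUP1 and SEO1 without array 3, SOA1 without array 4 and SUL2 without array 5. No named gene or list that passed changed direction in any setting run. Of 84 named genes past the threshold, 56 held on leaving out each array and 58 as deposited. Of the 32 sign patterns of the 6 arrays, only the real one called as many as 836 genes and the highest other called 0. With so few patterns the smallest possible p is 0.0312, so chance is not excluded even if the 6 arrays are independent. Turning the sign of a change that the arrays share also widens each gene's spread, which lowers the calls in the other patterns. A dye bias shared by all arrays is not excluded either. If the arrays come in pairs from 3 cultures, the sign patterns by pair are fewer still. No paired analysis was possible because there is 1 group and each array already holds both strains. Signal over background was not used here, so its limits are unknown.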

Other observations

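The list tests here were written before their results were seen but after the leading genes of each list were, and the genes named were chosen after their values were seen. Of 16 inositol and phospholipid genes other than INO1 and ITR1, 7 rose, none fell and 9 did not pass (9 rose adjusted over the list alone). CHO1, phosphatidylserine synthase, rose by 1.11 ± 0.60, PSD1 by 0.93 ± 0.80, OPI3 by 0.86 ± 0.81, CKI1 by 0.70 ± 0.29 and CPT1 by 0.46 ± 0.27. The regulators INO4 and OPI1 rose by 0.86 ± 0.35 and 0.79 ± 0.22, while INO2 stood at 0.05 ± 0.36 and CHO2 at 0.40 ± 0.52. Of 15 genes listed as cell wall integrity targets other than PST1, YGP1 and ZPS1, 8 rose, none fell and 7 did not pass (8 rose adjusted over the list alone). YGP1 also stands in the general stress list, so its rise does not point to the cell wall alone. PIR3 rose by 1.18 ± 0.43, BGL2 by 1.00 ± 0.21, NCW2 by 0.94 ± 0.34 and the kinase gene SLT2 by 0.65 ± 0.29. The calls of CKI1, CPT1, OPI1 and SLT2 did not hold in the values as deposited (limma, adjusted p = 0.120, 0.427, 0.0646 and 0.159). Nor did those of the remaining cell wall genes called, SED1, PIR1, CHS3 and CRG1 (limma, adjusted p = 0.226, 0.101, 0.361 and 0.103). Leaving out 1 array, CPT1 lost its call whichever it was, OPI3 without array 3, 4, 5 or 6 and PSD1 without array 4 or 6. SED1 lost its call without array 3, 5 or 6, and CHS3 and CRG1 lost theirs without array 3, 4, 5 or 6. OPI3, CHS3 and CRG1 also lost theirs with centring by print-order run.

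A candidate explanation for the high INO1 and ITR1 is a rise of the inositol and phospholipid genes together. Without those 2 the list had a median of 0.43 and was higher than other genes (camera, p = 3.06e-05, and p = 0.0555 with an estimated correlation). The same holds as a hypothesis for cell wall integrity targets, with a median of 0.50 (camera, p = 6.04e-06, and p = 0.00964 with an estimated correlation, both unadjusted). A rise of glycerol and osmotic stress genes together, tried after GPD1 and GUT2 were seen, was not found: 0 of 12 others rose and 2 fell (3 and 2 adjusted over the list alone), namely GPP1 (-0.65 ± 0.38) and GPP2 (-0.55 ± 0.47). Neither was called as deposited (limma, adjusted p = 0.494 and 0.677) or with centring by print-order run, and GPP2 not without array 2, 3, 4 or 5. GRE2, at 1.22 ± 1.72 after centring (limma, adjusted p = 0.0940), passed as higher in the values as deposited (adjusted p = 0.00117). For the glycerol and osmotic stress list limma's camera gave an adjusted p = 0.410 (also 0.410 before adjustment), and the median of 0.23 does not exclude a shared rise. Over the 3 lists the adjusted p-values at the preset correlation were 4.59e-05, 1.81e-05 and 0.410. The values with an estimated correlation were not adjusted, so they cannot be set beside the adjusted p = 0.403 of the lists fixed beforehand. Unadjusted, camera with an estimated correlation gave p = 0.0357 for general stress and 0.0314 for the phosphate regulon. Dye bias may contribute to each, because 0 arrays had the mutant in Cy5.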
